A study of Mus musculus with 21 samples.

How the data were processed

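RNA sequencing was available for 21 libraries of mouse spleen cells in 7 groups of 3. The groups were CD45+ and CD45- Ter119+CD71+ cells from tumor-bearing mice, from mice with anemia and from neonatal mice, and MDSC sorted as CD11b+Gr1+ cells from tumor-bearing mice. Libraries were made from total RNA with a TruSeq RNA kit, per the labels' protocols. The extraction text in the labels speaks of retinas while the tissue label of every library says spleen. Of 16 photoreceptor and retina genes, 6 were in the table and the highest value of any in any library was 1.83, for Sag. The labels do not say whether the 3 libraries of a group come from separate animals or separate sorts. The p-values therefore measure the spread between these libraries, which may be technical.

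Reads were aligned with Bowtie 0.12.2 to build mm8, per the submitters' processing notes. The deposited values are log2 expression values per gene, already in log2 when the authors deposited them, with a column per library. No source names the scale behind the log, the tool or the annotation used for quantification, the offset or any gene filter. Of 86209 values under 1 out of the log, 99.997% were whole multiples of 1e-06 within a tolerance of 0.01 of a step, and sums per library differed (227961 to 349261). Read counts and depth are not given, so no counting error could be computed. The table held 14273 genes, of which 10418 had a value in every library. There were 23668 blank cells (7.90%), which were taken as 0 because the logarithm of 0 has no value, so that "listed at 0" means a blank. For 8 repeated symbols the entry with the highest mean kept the symbol. A further 22 symbols had been turned into dates and were not named.

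Values were taken out of the log, a pseudocount of 1 was added and log2 was taken. Genes with a value of at least 1 in at least 3 libraries of the fit were tested, 11195 in the fit of the 18 Ter119+CD71+ libraries and 10255 in the fit of the 9 libraries from tumor-bearing mice, which served for the comparison with MDSC. No further scaling between libraries was applied. Each fit was a linear model with a mean per group in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with the trend and robust options of its moderated test. Groups were compared two-sided for CD45+ against CD45- cells in each status, for tumor against anemia and against neonatal CD45+ cells, and for tumor CD45+ cells against MDSC. A pair of interaction terms compared the CD45 contrast of tumor-bearing mice with that of mice with anemia and with that of neonates. P-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method, at a threshold of 0.05. Standard errors are those of the moderated fit. Principal components were computed on log2(value + 1) of 11294 genes passing the same filter over all 21 libraries.

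The comparisons, the gene lists, the rule for named genes and the alternatives in processing, except those named as later, were set before the data were examined. Named genes were the 8 with the largest positive and the 8 with the largest negative log2 fold change that passed (5 and 5 for the interactions), with libraries that do not overlap between the groups (not asked of interactions) and a mean of at least 10 in the higher group, leaving out symbols that carry only a clone or locus number. The antigens of the sort (Ptprc, Tfrc, Itgam and Ly6g) and retina genes were added, with up to 4 members with the smallest adjusted p of each list that passed and of the immune cell, suppression, oxidase, globin and cell cycle lists, and the text names part of these. The lists covered sort antigens, globins, embryonic globins and fetal genes, haem synthesis and iron, red cell membrane, erythroid transcription and terminal maturation, early progenitors, EPO-STAT5 targets, cell cycle, immunosuppressive mediators, NADPH oxidase, antioxidant genes, neutrophil granule and MDSC genes, monocytes and macrophages, B cells, T and NK cells, megakaryocytes and platelets, dendritic cells, mast cells and basophils, interferon response, MHC class I and class II presentation, glycolysis and hypoxia, inflammatory cytokines and chemokines, stress and immediate early genes, and ribosomal proteins. Of the 454 listed genes 424 were in the table. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with p adjusted over 207 tests. They were tested again with an estimated correlation and with fry, whose p asks whether a list moves one way on balance without comparing it with other genes. Hepatocyte (24 genes) and Kupffer cell (8 genes) lists were added after the data were seen.

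Similarity to MDSC was the Spearman correlation across genes with the mean of the 3 MDSC libraries, compared between groups with exact two-sided permutation tests. A gene was counted as single-exon when GENCODE vM21 (GRCm38) basic annotation held a protein-coding transcript of 1 exon for its symbol.

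Replicate numbers are shared between groups in the labels without a stated meaning. Deviations from group means correlated between libraries of the same number by at least 0.112 in tumor CD45+ and CD45- cells, 0.109 in anemia, 0.215 in neonatal cells, 0.106 between tumor and neonatal CD45+ cells and 0.166 between tumor CD45+ cells and MDSC, all above the limit of 0.1, so an alternative block fit paired libraries by number. This pairing is not in the labels, and the limit cannot tell it from an effect shared by replicate 3. Only neonatal cells, and tumor CD45+ cells with MDSC, had each library correlate best with its own number. Tumor and anemia CD45+ cells were below 0.1 (0.0489).

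The scripts were tested on simulated data in which 100 genes were changed 2-fold and 100 4-fold. Of the 4-fold changes, 82 of 100 were recovered for tumor, 79 for anemia and 86 for neonatal CD45+ against CD45- cells (10716, 10685 and 10819 genes), and 23, 28 and 23 of the 2-fold changes. Tumor against anemia and neonatal CD45+ cells gave 87 and 87 of the 4-fold and 28 and 26 of the 2-fold changes (10714 and 10728 genes), and tumor CD45+ cells against MDSC 84 and 28 (10090 genes). The interactions with anemia and neonates gave 43 and 59 of the 4-fold but only 4 and 2 of the 2-fold changes (10725 and 10718 genes). Between 2 and 12 unchanged genes were called, and the changed list was found in all 8, though real data need not vary as simulated.

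Alternatives were median-ratio scaling, quantile normalization, leaving out haemoglobin genes and rescaling, a pseudocount of 0.1, no filter, a stricter filter (at least 5 in 3 libraries), fits of only the compared groups or of all 21 libraries, no trend and robust options, the replicate block, and leaving out each library in turn. Fits of replicates 1 and 2 alone, fits without genes that had a blank beside a value of at least 20 in the same group, and list tests without each library were added after the data were seen. For every comparison the labels were also regrouped, over all 10 splits of 6 libraries or, for the interactions, over 100 drawn splits.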

Results

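RNA was sequenced from sorted spleen cells of C57BL/6 mice in 21 libraries, 3 for each of 7 groups. In 6 groups the cells carried Ter119, a surface antigen of erythroid cells, together with CD71, the transferrin receptor encoded by Tfrc that erythroid precursors carry at high density. These cells were divided by CD45, the leukocyte phosphatase encoded by Ptprc that is lost as erythroid cells mature, into CD45+ and CD45- fractions, and were taken from tumor-bearing mice, mice with anemia and neonatal mice. The remaining group held myeloid-derived suppressor cells (MDSC), CD11b+Gr1+ cells from the spleens of tumor-bearing mice. The series set out to compare CD45+ erythroid-like progenitors of tumor-bearing mice, described in its design as suppressive, with other cell types and with the same sort in other states. Levels below are the deposited log2 values taken out of the log, on an expression scale that the sources used here do not name. They summed to between 227961 and 349261 per library, and 12294 to 13952 of the 14273 listed genes had a value in a library. Read depth is unknown, so no counting interval is given, and the spread between the 3 libraries of a group carries all of the error. Pearson correlations across genes between libraries of a group ran from 0.867 in tumor CD45+ cells to 0.974 in anemia CD45- cells, with genes not being independent replicates.

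The first principal component held 63.1% of the variance over 11294 genes and parted the CD45- libraries from all other libraries. The 9 CD45- libraries scored between 79.5 and 111.9 on it, against -85.9 to -47.8 for the 9 CD45+ and 3 MDSC libraries. The second component, with 12.1% of the variance, ran from the MDSC libraries (-66.1 to -62.0) to the anemia CD45+ libraries (56.5 to 68.7). Neonatal CD45+ libraries lay between -0.658 and 21.5 on it. The 3 tumor CD45+ libraries did not lie together on it, at -27.5, -18.2 and 41.7 for replicates 1, 2 and 3. Replicate 3 also held the lowest globin and histone shares of its group in 7 of 7 groups and the highest mitochondrial share in 6 of 7.

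**Figure D1:**
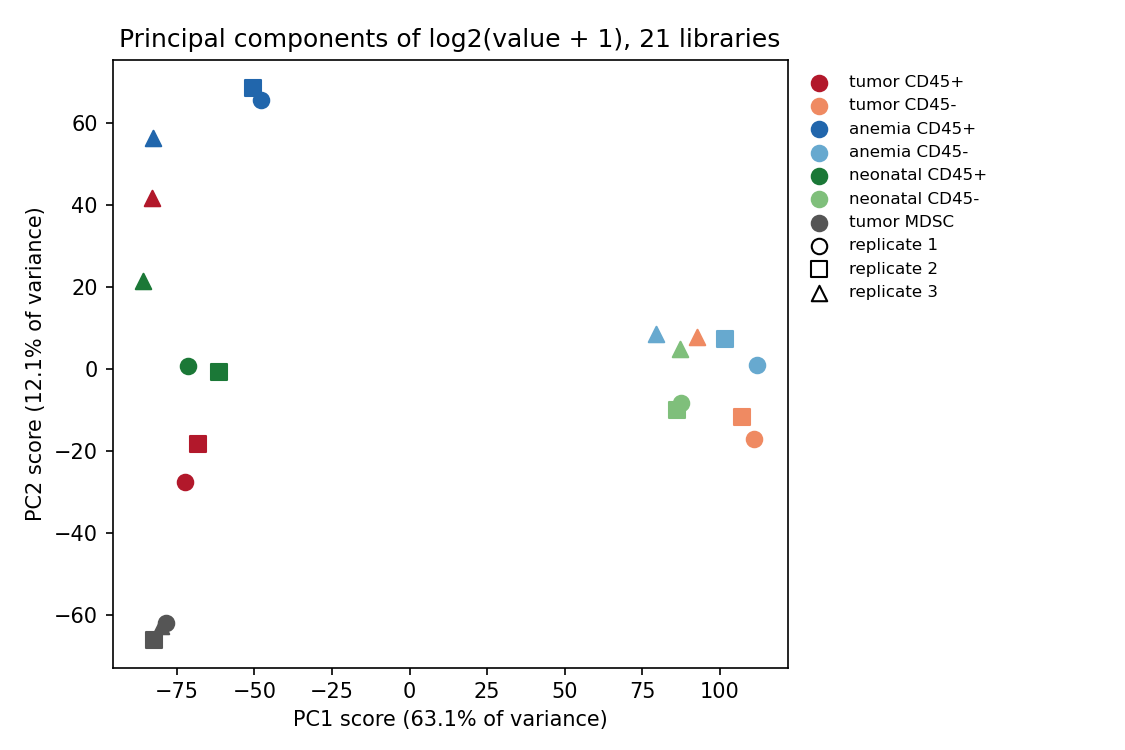
Scores of the 21 libraries on the first and second principal components of log2(value + 1), with colors for the groups and symbols for the replicate numbers. CD45- libraries lie between 79.5 and 111.9 on the first component and all CD45+ and MDSC libraries between -85.9 and -47.8.

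Ptprc transcripts followed the CD45 gate. Ptprc stood at 231 ± 136, 390.5 ± 78.9 and 125 ± 54.6 in tumor, anemia and neonatal CD45+ cells, at 1.85 ± 0.964, 3.76 ± 1.57 and 2.27 ± 0.822 in the matching CD45- cells, and at 183 ± 39.8 in MDSC (SD, n = 3). It rose by 6.24 ± 0.39, 6.39 ± 0.39 and 5.21 ± 0.39 log2 units (SE) from CD45- to CD45+ cells, with limma adjusted p = 1.0e-09, 1.0e-09 and 1.3e-08. Tfrc was present on both sides of the CD45 gate but lower in CD45+ cells, with log2 fold changes of -3.21 ± 0.47, -2.68 ± 0.47 and -3.13 ± 0.47 (SE, adjusted p = 1.6e-05, 1.1e-04 and 2.4e-05). Itgam, which encodes the CD11b of the MDSC gate, reached 96.2 ± 31.7 in tumor CD45+, 23.5 ± 21.3 in anemia CD45+ and 75.6 ± 27.1 in neonatal CD45+ cells against 239 ± 38.1 in MDSC (SD, n = 3). Ly6g, part of the Gr1 epitope, was 1.05, 10.9 and 21.7 in the 3 tumor CD45+ libraries and 8.33, 7.81 and 37.8 in the 3 MDSC libraries, so these groups overlapped.

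**Figure D2:**
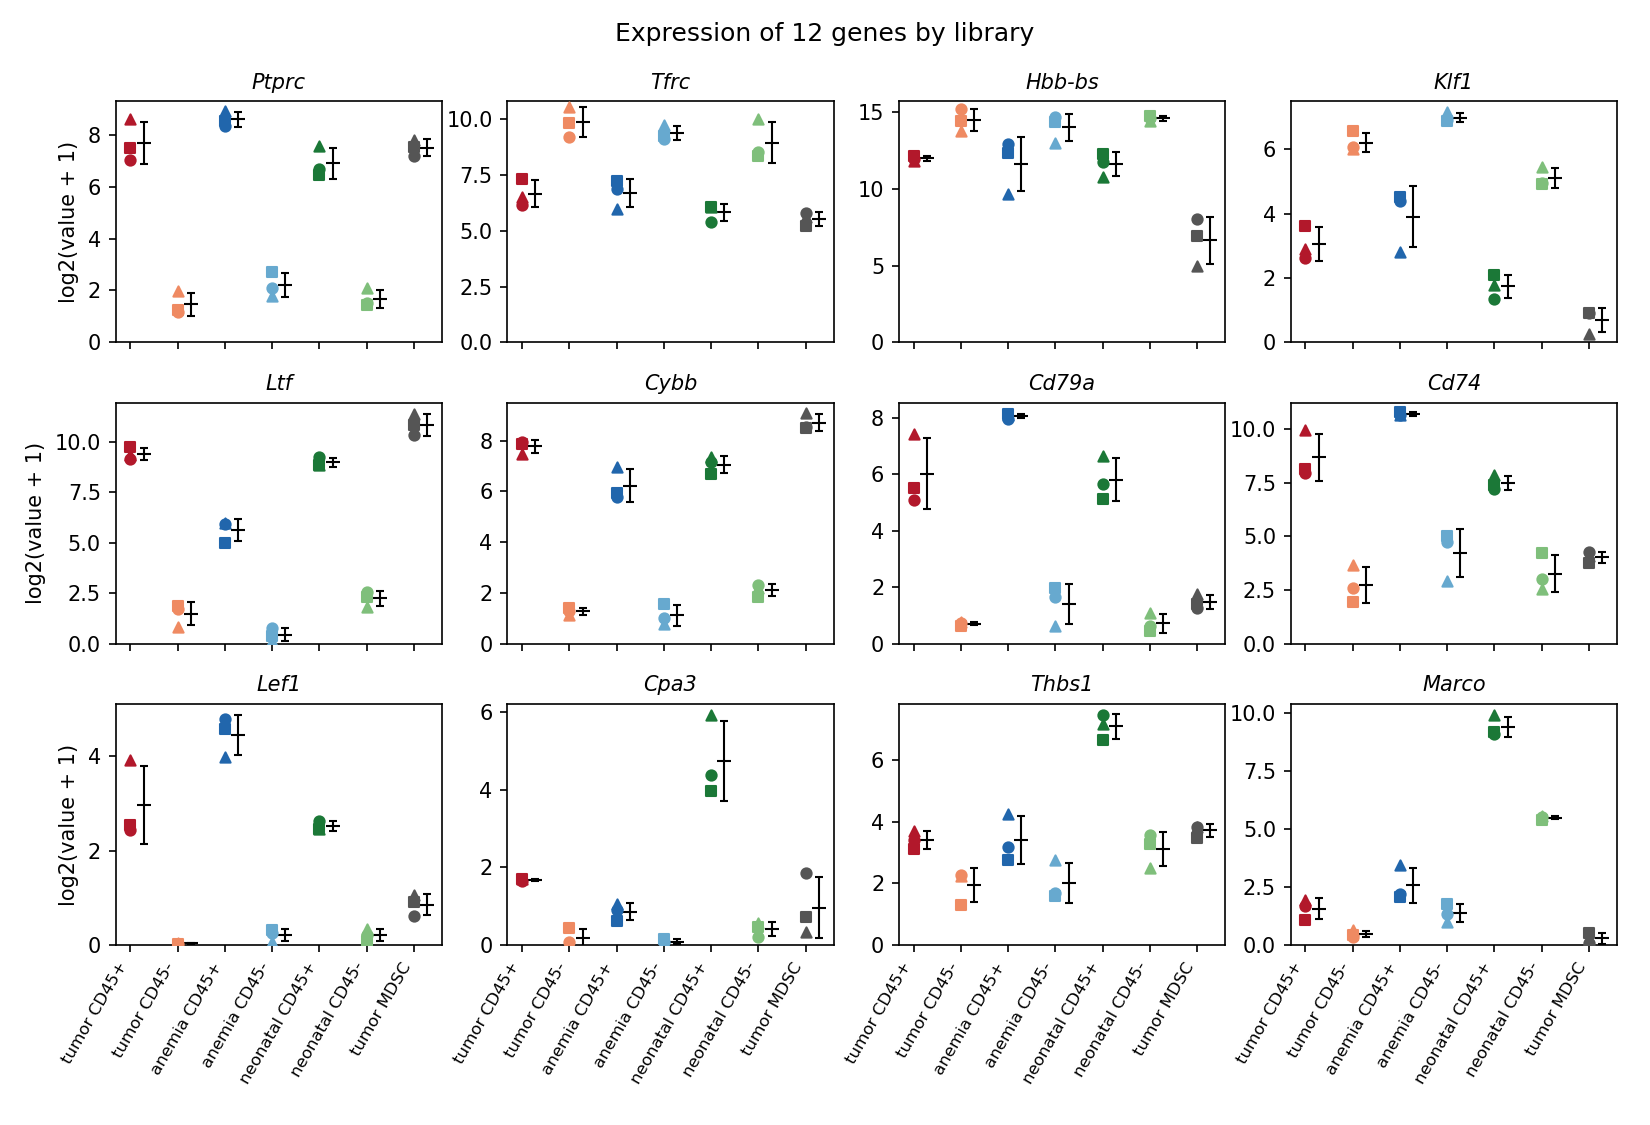
Expression of 12 genes in every library as log2(value + 1), with a point per library, symbols for replicates 1 (circle), 2 (square) and 3 (triangle), and a bar beside them for the mean and SD of the 3 libraries. Ptprc, Ltf, Cybb, Cd79a, Cd74 and Lef1 are higher in each CD45+ group than in its CD45- group, Tfrc, Hbb-bs and Klf1 are lower, and Marco is highest in the neonatal CD45+ libraries.

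The first comparison set CD45+ against CD45- Ter119+CD71+ cells of tumor-bearing mice. CD45+ cells held far more transcript of leukocyte genes, led by neutrophil granule genes, and far less of erythroid genes. Ltf, which encodes the granule protein lactoferrin, stood at 687 ± 141 in CD45+ and 1.92 ± 0.996 in CD45- cells (SD, n = 3), a rise of 7.93 ± 0.32 log2 units (SE, adjusted p = 2.2e-11). S100a8, a calcium-binding protein abundant in neutrophils and MDSC, stood at 7599.5 ± 3645 against 73.6 ± 63.4. Klf1, the erythroid Krüppel-like transcription factor, fell from 73.7 ± 16.4 to 7.65 ± 3.26 (-3.15 ± 0.38 log2 units, adjusted p = 2.1e-06).

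All 21 tested members of the neutrophil granule and MDSC list rose (camera adjusted p = 2.4e-09, 0.29 with an estimated correlation), and 21 rose and 0 fell adjusted over the list alone. Chil3 rose by 7.98 ± 0.55, Camp by 7.77 ± 0.45, Lcn2 by 7.59 ± 0.57 and Ngp by 7.09 ± 0.67 log2 units (SE). The list made up 9.57% ± 3.78 of the summed values in tumor CD45+, 0.0787% ± 0.0567 in tumor CD45- and 22.1% ± 4.29 in MDSC (SD, n = 3). Outside the lists, the annexin gene Anxa1 (7.16) and the leukocyte receptor gene Lilr4b (7.42) were among the 8 largest rises. Of the 8 tested NADPH oxidase genes, which encode the complex that makes superoxide in phagocytes, 7 rose, 0 fell and 1 did not pass (camera adjusted p = 0.0028, 0.31 with an estimated correlation). Cybb, its catalytic subunit, rose from 1.42 ± 0.220 to 219.5 ± 36.4 (6.50 ± 0.31) and Ncf4 by 5.75 ± 0.33. Lymphocyte genes rose as well. Among B cell genes 17 rose, 0 fell and 0 did not pass (camera adjusted p = 2.8e-05, 0.43 with an estimated correlation). Cd37 rose by 5.02 ± 0.26 and Pax5, the B lineage transcription factor, by 4.08 ± 0.33. Among T and NK cell genes 25 rose, 0 fell and 1 did not pass (camera adjusted p = 0.0018, 0.62 with an estimated correlation). Lef1 rose by 2.93 ± 0.31 and Ccr7 by 2.97 ± 0.33. All 8 MHC class II presentation genes rose (camera adjusted p = 0.0011, 0.43 with an estimated correlation), among them Cd74, the invariant chain, from 6.48 ± 4.52 to 505 ± 417 (SD, n = 3). The MHC class I list had 10 members that rose, 0 that fell and 2 that did not pass (camera adjusted p = 0.0064, 0.47 with an estimated correlation). Psmb8 rose by 3.97 ± 0.24.

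Immunosuppressive mediators numbered 23 tested genes, of which 19 rose, 1 fell and 3 did not pass (camera adjusted p = 0.019, 0.33 with an estimated correlation), and 19 rose and 1 fell adjusted over the list alone. Il4ra, the interleukin 4 receptor chain linked to MDSC activity, rose by 4.39 ± 0.25, Stat3 by 3.94 ± 0.27, the galectin genes Lgals3 by 5.52 ± 0.41 and Lgals1 by 3.95 ± 0.30. Monocyte and macrophage genes had 18 members that rose, 0 that fell and 4 that did not pass (camera adjusted p = 0.031, 0.62 with an estimated correlation). Lyz2, which encodes lysozyme, rose by 5.28 ± 0.45. Inflammatory cytokine genes had 16 members that rose, 0 that fell and 1 that did not pass (camera adjusted p = 0.023, 0.57 with an estimated correlation). Nfkb1 rose by 3.18 ± 0.38. Glycolysis and hypoxia genes had 19 members that rose, 1 that fell and 1 that did not pass (camera adjusted p = 6.7e-04, 0.35 with an estimated correlation), led by Pkm, pyruvate kinase, from 4.18 ± 1.78 to 353 ± 176, and Gpi1 up by 4.92 ± 0.40. Without tumor CD45- replicate 3 the immunosuppressive and inflammatory lists no longer passed (adjusted p = 0.060 and 0.061), and the monocyte list did not pass without tumor CD45+ replicate 3 (0.068) or anemia CD45- replicate 3 (0.058).

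On the erythroid side, all 4 tested adult globin genes fell (camera adjusted p = 0.0018, 0.33 with an estimated correlation). Hbb-bs fell from 24641 ± 12002 to 4065 ± 461 (SD, n = 3). Hbb-bt fell by 3.17 ± 0.81 log2 units (SE). Haem synthesis and iron genes had 0 members that rose, 15 that fell and 3 that did not pass (camera adjusted p = 1.3e-12, 0.20 with an estimated correlation). Alad changed by -3.66 ± 0.50. Red cell membrane genes had 0 members that rose, 17 that fell and 2 that did not pass (camera adjusted p = 2.1e-14, 0.29 with an estimated correlation). Rhag changed by -3.70 ± 0.60 and Add2 by -3.54 ± 0.53. Erythroid transcription and terminal maturation genes had 1 member that rose, 18 that fell and 2 that did not pass (camera adjusted p = 8.4e-14, 0.20 with an estimated correlation). Zfpm1 changed by -3.35 ± 0.41 and Gata1, the erythroid GATA factor, by -3.29 ± 0.48. Cell cycle genes also fell, 28 of 34 with 6 not passed (camera adjusted p = 4.0e-16, 0.29 with an estimated correlation). Mki67 fell from 1049 ± 181 to 207 ± 89.4. The largest falls outside histone genes were Fam46c (-5.29 ± 1.61, adjusted p = 0.011, and 0.052 without tumor CD45- replicate 1, where it did not pass), Btnl10 (-4.31 ± 0.66), Hemgn (-4.10 ± 0.62) and the glycine transporter gene Slc6a9 (-4.05 ± 0.74). Histone genes such as Hist3h2ba were listed at 0 in all 3 CD45+ libraries, against 189, 237 and 67.2 in the CD45- libraries, and are held uncertain, since such single-exon genes were blank in some libraries and high in others of the same group. EPO-STAT5 targets had 6 members that rose, 6 that fell and 3 that did not pass, with Fam132b at -3.46 ± 0.49 and Stat5a at 1.71 ± 0.31. Their median was 0.40 and their mean -0.13, and under quantile normalization the median was -0.61, while camera placed the list lower than other genes (camera adjusted p = 0.037, 0.45 with an estimated correlation), a call that did not hold with fry (adjusted p = 0.89), under median-ratio scaling (0.099) or quantile normalization (0.19) or without tumor CD45+ replicate 1 (0.055), tumor CD45+ replicate 3 (0.070) or tumor CD45- replicate 2 (0.080). Antioxidant genes had 1 member that rose, 7 that fell and 8 that did not pass (camera adjusted p = 6.5e-04, 0.073 with an estimated correlation). Prdx2, an abundant red cell peroxiredoxin, changed by -3.55 ± 0.46, Gclm by -2.52 ± 0.40 and Hmox1 by 2.66 ± 0.59. Their median was 0.01 and their mean -0.32, with medians of -0.43 and -0.65 under median-ratio scaling and quantile normalization.

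In the limma test 6839 of 11195 genes passed at an adjusted p below 0.05, 5621 higher and 1218 lower in tumor CD45+ cells, and 4431 and 906 of these differed at least 2-fold. The direction of the whole set depended on scaling, with 4601 higher and 1827 lower under median-ratio scaling, 4528 and 1947 with haemoglobin genes left out, and 2617 and 3060 under quantile normalization. The median log2 fold change of all genes was 0.75, 0.45, 0.42 and -0.08 in these 4 settings. Relative to the first of these, the median of the neutrophil list was 5.68, that of the B cell list 3.13 and that of the cell cycle list -2.14.

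In mice with anemia the B cell and MHC class II lists had the largest median rises of the same contrast, at 5.38 and 5.06 log2 units. Cd79a, a chain of the B cell receptor, stood at 266 ± 15.9 in CD45+ and 1.86 ± 1.22 in CD45- cells (SD, n = 3), a rise of 6.65 ± 0.50 log2 units (SE, adjusted p = 9.0e-09). Cd74 stood at 1667 ± 93.8 against 21.3 ± 13.1. Zfp36, a regulator of mRNA decay, rose by 6.70 ± 0.41, the class I gene H2-Q6 by 6.14 ± 0.38 and S100a8 by 6.25 ± 0.72. Ctse, which encodes cathepsin E, fell by 3.67 ± 0.61 and the haem exporter gene Abcg2 by 3.49 ± 0.53 log2 units.

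All 17 B cell genes rose (camera adjusted p = 7.1e-08, 0.33 with an estimated correlation). Cd37 rose by 5.38 ± 0.26 and Ebf1 by 4.88 ± 0.33. All 26 T and NK cell genes rose (camera adjusted p = 9.0e-09, 0.37 with an estimated correlation). Lef1 rose by 4.24 ± 0.31. The 8 MHC class II and 12 MHC class I genes all rose (camera adjusted p = 1.0e-04, 0.35 with an estimated correlation for class II and 1.6e-04 and 0.33 for class I), H2-DMa by 4.63 ± 0.36 and H2-K1 by 4.16 ± 0.30. Dendritic cell genes had 12 members that rose, 0 that fell and 1 that did not pass (camera adjusted p = 0.0064, 0.49 with an estimated correlation). Irf8 rose by 3.99 ± 0.41 and Itgax by 3.83 ± 0.41. All 21 neutrophil granule genes rose here too (camera adjusted p = 2.7e-05, 0.39 with an estimated correlation), Ltf to 51.1 ± 17.4 and Retnlg by 4.82 ± 0.42, and the list made up 0.717% ± 0.696 of the summed values. NADPH oxidase genes had 7 members that rose, 0 that fell and 1 that did not pass (camera adjusted p = 0.0032, 0.31 with an estimated correlation), with Cybb up by 5.11 ± 0.31, and immunosuppressive mediators had 18 that rose, 1 that fell and 4 that did not pass (camera adjusted p = 0.0052, 0.29 with an estimated correlation). Il4ra rose by 4.58 ± 0.25 and Stat3 by 3.80 ± 0.27. Inflammatory genes had 15 members that rose, 0 that fell and 2 that did not pass (camera adjusted p = 0.013, 0.53 with an estimated correlation). Tnfaip3 rose by 5.10 ± 0.54. Without anemia CD45- replicate 3 the list did not pass, with an adjusted p of 0.0503. Glycolysis and hypoxia genes had 18 members that rose, 1 that fell and 2 that did not pass (camera adjusted p = 0.045, 0.57 with an estimated correlation). Pfkp rose by 3.83 ± 0.29. The glycolysis list did not pass with the replicate block (0.056) or without anemia CD45+ replicate 2 (0.055) or 3 (0.051), anemia CD45- replicate 1 (0.063) or 2 (0.056) or tumor CD45- replicate 1 (0.052).

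Erythroid genes fell as in the tumor comparison. The 4 globin genes fell (camera adjusted p = 0.0042, 0.37 with an estimated correlation). Hbb-bs fell from 18570.0 ± 9404 to 4633 ± 3606 (SD, n = 3). Haem synthesis genes had 1 member that rose, 15 that fell and 2 that did not pass (camera adjusted p = 3.1e-11, 0.20 with an estimated correlation). Slc25a38 changed by -2.34 ± 0.39. Red cell membrane genes had 0 members that rose, 18 that fell and 1 that did not pass (camera adjusted p = 4.6e-13, 0.29 with an estimated correlation), and erythroid transcription genes had 2 that rose, 18 that fell and 1 that did not pass (camera adjusted p = 8.1e-12, 0.25 with an estimated correlation). Klf1 changed by -3.08 ± 0.38. All 34 cell cycle genes fell (camera adjusted p = 6.7e-24, 0.20 with an estimated correlation). Top2a fell from 391 ± 38.8 to 92.5 ± 38.7 and Bub1 by 2.11 ± 0.28 log2 units. Antioxidant genes had 1 member that rose, 7 that fell and 8 that did not pass (camera adjusted p = 1.6e-04, 0.046 with an estimated correlation). Gclc changed by -1.78 ± 0.26 and Gpx1 by -1.63 ± 0.30. In all, 6577 of 11195 genes passed at an adjusted p below 0.05, 5310 higher and 1267 lower in anemia CD45+ cells, and 4237 and 984 of these differed at least 2-fold. The split was 4391 higher and 1823 lower under median-ratio scaling, 4495 and 1791 with haemoglobin genes left out, and 2647 and 2990 under quantile normalization, with the median of all genes at 0.68, 0.40, 0.43 and -0.07 unscaled and in these 3 settings.

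In neonatal mice, neutrophil granule, mast cell and basophil and most monocyte and macrophage genes were higher in CD45+ than in CD45- cells, though no list passed with an estimated correlation. Prg2, the major basic protein of eosinophil granules, stood at 996 ± 326 in CD45+ and 3.33 ± 0.806 in CD45- cells (SD, n = 3), a rise of 7.81 ± 0.64 log2 units (SE, adjusted p = 3.5e-08). Mpo, myeloperoxidase, stood at 705 ± 260.4 against 3.90 ± 2.52, and Prtn3 rose by 6.37 ± 0.66. Cpa3, the mast cell carboxypeptidase, stood at 31.1 ± 24.4 against 0.343 ± 0.169 (4.33 ± 0.34). Sptb, which encodes beta spectrin, fell by 4.19 ± 0.72, Ank1 by 4.14 ± 0.66, the blood group gene Kel by 4.05 ± 0.68 and Sox6, an erythroid transcription factor, by 4.04 ± 0.71 log2 units.

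All 21 neutrophil granule genes rose (camera adjusted p = 2.3e-08, 0.30 with an estimated correlation), Camp by 6.95 ± 0.45, Chil3 by 6.89 ± 0.55 and Ltf by 6.74 ± 0.32, and the list made up 4.40% ± 0.594 of the summed values against 0.0536% ± 0.0105 in CD45- cells. All 8 mast cell and basophil genes rose (camera adjusted p = 3.0e-04, 0.20 with an estimated correlation). Gata2 rose by 2.80 ± 0.22. Monocyte and macrophage genes had 18 members that rose, 0 that fell and 4 that did not pass (camera adjusted p = 0.0077, 0.53 with an estimated correlation). Lyz2 rose by 5.24 ± 0.45 and Fcgr1 by 2.93 ± 0.35. The early progenitor list passed here (camera adjusted p = 0.0047, 0.20 with an estimated correlation), with 15 members that rose, 1 that fell and 2 that did not pass, Spi1, the myeloid factor PU.1, up by 4.41 ± 0.33 and Fli1 by 3.04 ± 0.26. B cell genes had 15 members that rose, 0 that fell and 2 that did not pass (camera adjusted p = 6.0e-04, 0.52 with an estimated correlation). Cd79a rose by 5.09 ± 0.50. MHC class II genes had 8 members that rose, 0 that fell and 0 that did not pass (camera adjusted p = 0.010, 0.52 with an estimated correlation) and class I genes had 10 that rose, 0 that fell and 2 that did not pass (camera adjusted p = 0.0022, 0.41 with an estimated correlation). H2-K1 rose by 3.53 ± 0.30. NADPH oxidase genes had 7 members that rose, 0 that fell and 1 that did not pass (camera adjusted p = 0.0029, 0.31 with an estimated correlation), Cybb up by 4.94 ± 0.31, and immunosuppressive mediators had 18 that rose, 0 that fell and 5 that did not pass (camera adjusted p = 0.011, 0.31 with an estimated correlation). Lgals1 rose by 3.47 ± 0.30 and Lgals3 by 4.49 ± 0.41. All 17 inflammatory genes rose (camera adjusted p = 8.6e-04, 0.41 with an estimated correlation). Tnfaip3 rose by 5.18 ± 0.54.

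Globin genes fell in neonates as well, all 4 of them (camera adjusted p = 6.5e-04, 0.31 with an estimated correlation). Hbb-bs fell from 24885 ± 2613 to 3404 ± 1657 (SD, n = 3). Haem synthesis genes had 0 members that rose, 15 that fell and 3 that did not pass (camera adjusted p = 3.5e-13, 0.20 with an estimated correlation), with Urod at -3.53 ± 0.51, red cell membrane genes had 0 that rose, 17 that fell and 2 that did not pass (camera adjusted p = 4.8e-16, 0.26 with an estimated correlation), with Rhag at -3.84 ± 0.60, and erythroid transcription genes had 0 that rose, 18 that fell and 3 that did not pass (camera adjusted p = 2.7e-14, 0.20 with an estimated correlation). Gfi1b changed by -3.23 ± 0.47. Cell cycle genes had 0 members that rose, 23 that fell and 11 that did not pass (camera adjusted p = 2.1e-15, 0.29 with an estimated correlation). Ccna2 changed by -2.27 ± 0.41. Antioxidant genes had 4 members that rose, 6 that fell and 6 that did not pass (camera adjusted p = 0.0022, 0.11 with an estimated correlation). Prdx2 changed by -2.73 ± 0.46. In all, 6710 of 11195 genes passed at an adjusted p below 0.05, 5554 higher and 1156 lower in neonatal CD45+ cells, and 4409 and 851 of these differed at least 2-fold. The split was 4435 higher and 1819 lower under median-ratio scaling, 4365 and 1961 with haemoglobin genes left out, and 2663 and 2808 under quantile normalization, with the median of all genes at 0.75, 0.41, 0.39 and -0.02 unscaled and in these 3 settings. Quantile normalization ended the camera call of the globin list in the tumor, anemia and neonatal contrasts (adjusted p = 0.42, 0.41 and 0.34) and of the antioxidant list in the tumor and neonatal contrasts (0.095 and 0.24).

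**Figure D3:**
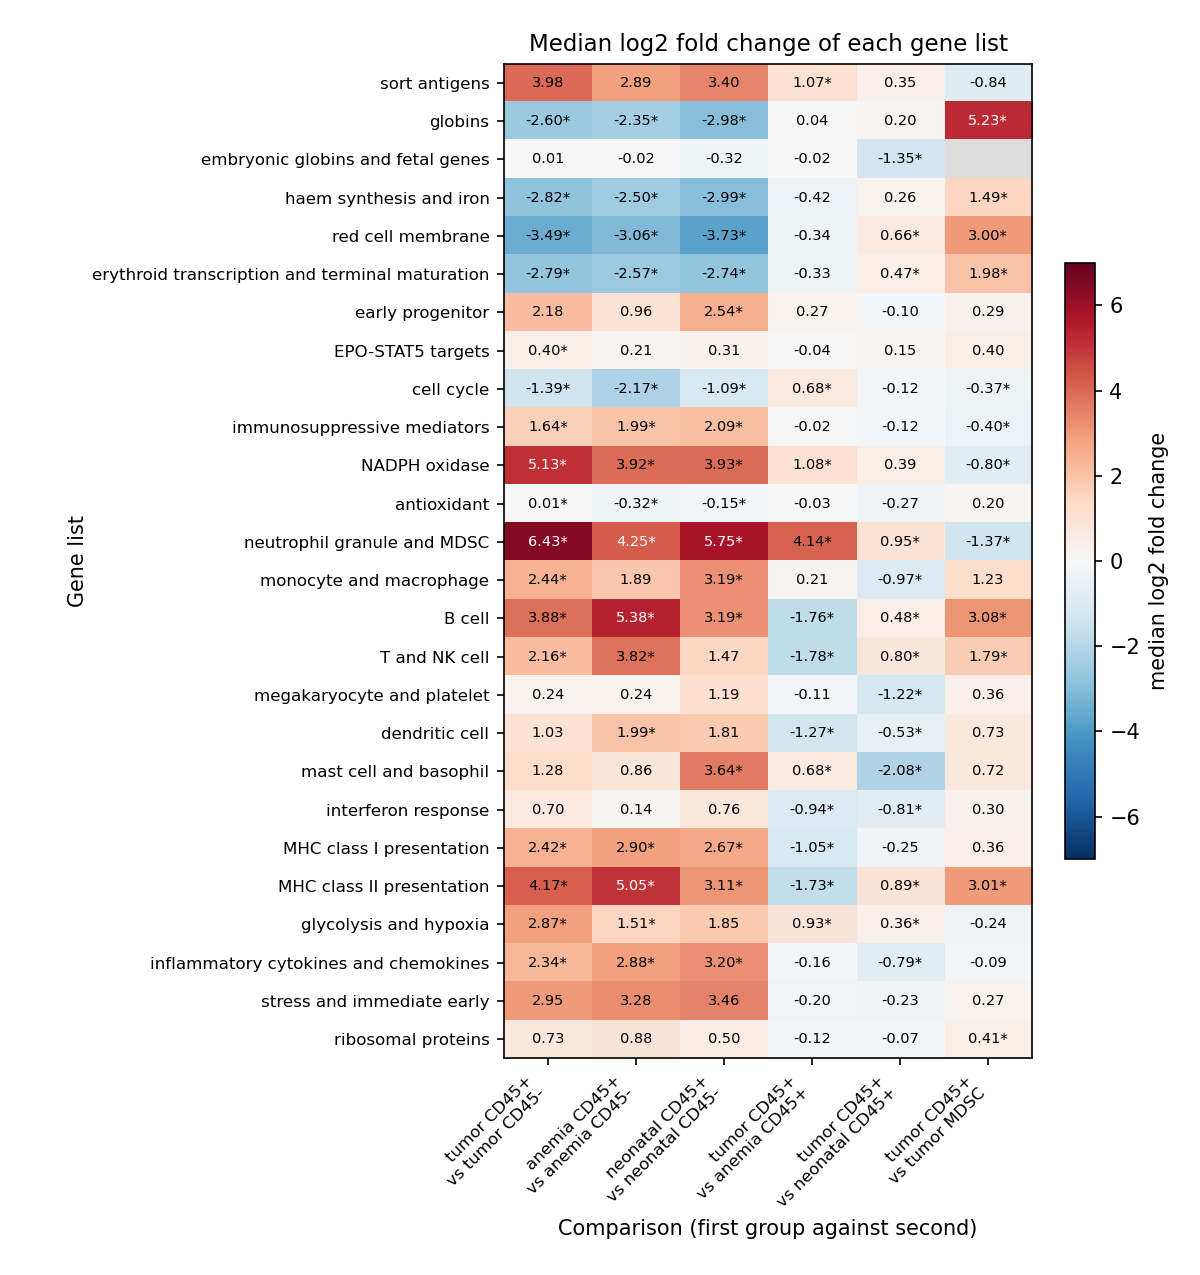
Median log2 fold change of the members of 26 gene lists (y axis) in the 6 pairwise comparisons (x axis), printed in each cell and shown as color, with an asterisk where the camera adjusted p was below 0.05 with the preset correlation and gray where fewer than 3 members were tested. The neutrophil granule list has medians of 6.43, 4.25 and 5.75 in the 3 contrasts of CD45+ with CD45- cells and 4.14 between tumor and anemia CD45+ cells; EPO-STAT5, interferon, megakaryocyte, antioxidant and embryonic medians turn negative in some CD45 contrasts under other scalings.

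The CD45+ cells of tumor-bearing mice were then compared with those of mice with anemia. Most neutrophil granule genes were higher in the tumor state, most lymphocyte and MHC class II genes were lower, and most interferon, MHC class I and erythroid genes did not pass the test. No list difference by camera held with an estimated correlation. Mpo stood at 638 ± 375 in tumor and 10.1 ± 4.17 in anemia CD45+ cells (SD, n = 3), a rise of 5.70 ± 0.64 log2 units (SE, adjusted p = 2.6e-05). Prtn3, the granule protease proteinase 3, rose by 5.39 ± 0.66 (adjusted p = 5.5e-05). Ly6a, the stem cell antigen Sca-1, fell from 36.6 ± 10.8 to 6.18 ± 6.53 and Thy1, carried by T cells, from 56.8 ± 19.5 to 10.8 ± 9.60 (adjusted p = 7.6e-04 and 9.9e-04).

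Of 21 neutrophil granule genes 18 rose, 0 fell and 3 did not pass (camera adjusted p = 1.6e-25, 0.11 with an estimated correlation), and 19 rose and 0 fell adjusted over the list alone. Ltf rose by 3.77 ± 0.32 and Camp by 4.37 ± 0.45, and Cd177, Ctsg and Elane were among the 8 largest rises of the comparison with log2 fold changes of 4.81, 5.86 and 5.32. NADPH oxidase genes had 4 members that rose, 0 that fell and 4 that did not pass (camera adjusted p = 0.0020, 0.30 with an estimated correlation). Cybb rose by 1.54 ± 0.31 and Ncf4 by 1.31 ± 0.33. Of the sort antigens, 3 of 7 rose (camera adjusted p = 0.019, 0.20 with an estimated correlation), Ly6c2 by 1.84 ± 0.25 and Itgam by 2.27 ± 0.42, and without tumor CD45+ replicate 3 the list did not pass (adjusted p = 0.086). Ptprc and Tfrc did not pass (-0.89 ± 0.39 and -0.03 ± 0.47). Glycolysis and hypoxia genes had 6 members that rose, 0 that fell and 15 that did not pass (camera adjusted p = 4.2e-04, 0.34 with an estimated correlation). Gpi1 rose by 2.04 ± 0.40 and Tpi1 by 2.11 ± 0.50. Mast cell and basophil genes had 3 members that rose, 0 that fell and 5 that did not pass (camera adjusted p = 0.0016, 0.20 with an estimated correlation). Cell cycle genes had 2 members that rose, 0 that fell and 32 that did not pass (camera adjusted p = 4.8e-06, 0.47 with an estimated correlation). Plk1 rose by 1.36 ± 0.32 and Kif20a by 1.23 ± 0.35, and the list's fry adjusted p was 0.11.

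T and NK cell genes had 0 members that rose, 21 that fell and 5 that did not pass (camera adjusted p = 6.2e-18, 0.27 with an estimated correlation), and 0 rose and 25 fell adjusted over the list alone. B cell genes had 0 members that rose, 15 that fell and 2 that did not pass (camera adjusted p = 6.0e-12, 0.29 with an estimated correlation). Pax5 changed by -1.49 ± 0.33 and Ebf1 by -1.48 ± 0.33. The list made up 0.202% ± 0.181 of the summed values in tumor and 0.617% ± 0.0484 in anemia CD45+ cells. All 8 MHC class II genes fell (camera adjusted p = 5.8e-07, 0.29 with an estimated correlation). Ciita, their master regulator, fell by 1.56 ± 0.36 log2 units. MHC class I genes had 0 members that rose, 5 that fell and 7 that did not pass (camera adjusted p = 1.2e-06, 0.29 with an estimated correlation), with H2-K1 at -1.26 ± 0.30, and 0 rose and 11 fell adjusted over the list alone. Dendritic cell genes had 1 member that rose, 6 that fell and 6 that did not pass (camera adjusted p = 1.1e-05, 0.31 with an estimated correlation). Bst2 changed by -1.48 ± 0.34 and, in the other direction, Clec4a2 by 2.15 ± 0.38. Interferon response genes had 0 members that rose, 8 that fell and 15 that did not pass (camera adjusted p = 7.4e-07, 0.32 with an estimated correlation). Usp18 changed by -1.96 ± 0.53 and Oasl1 by -1.59 ± 0.32. None of the 4 globin, 19 red cell membrane or 21 erythroid transcription genes passed, and 1 of 18 haem synthesis genes fell. Among immunosuppressive mediators 2 rose, 3 fell and 18 did not pass, with Lgals3 at 1.85 ± 0.41 (camera adjusted p = 0.60).

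In the limma test 1201 of 11195 genes passed at an adjusted p below 0.05, 651 higher and 550 lower in tumor CD45+ cells, and 558 and 409 of these differed at least 2-fold. The 3 tumor CD45+ libraries weighed unequally, since 546 genes passed without replicate 1 (382 higher and 164 lower), 602 without replicate 2 (405 and 197) and 2227 without replicate 3 (1024 and 1203), and 733 and 671 passed without anemia CD45+ replicates 1 and 2. With replicates 1 and 2 alone 3508 passed (1663 and 1845), an alternative chosen after the data were seen. Only 75 passed in a fit of only these 6 libraries (70 and 5), where the spread came from these groups alone with fewer degrees of freedom. Most of the 1201 calls, and nearly all of the 550 lower ones, did not pass there and relied on the spread shared over the 18 libraries. With a pseudocount of 0.1, 723 passed (486 and 237), so the balance of higher and lower genes depended on the setting.

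Against neonatal CD45+ cells, tumor CD45+ cells held far less transcript of liver-type macrophage, hepatocyte, mast cell and basophil genes. Few B cell and neutrophil genes rose, and neither list passed with fry. Marco, a scavenger receptor of macrophages, stood at 2.06 ± 0.878 in tumor and 697 ± 227 in neonatal CD45+ cells (SD, n = 3), and fell by 7.83 ± 0.35 log2 units (SE, adjusted p = 2.1e-10). Clec4f, a Kupffer cell lectin, and Ahsg, the liver glycoprotein fetuin A, were listed at 0 in all 3 tumor CD45+ libraries, against 219.7, 130.4 and 97.9 for Clec4f and 18.9, 23.9 and 71.2 for Ahsg in the neonatal ones. Cdh5, the endothelial cadherin, fell from 36.5 ± 0.707 to 0.188 ± 0.174. Jchain, which joins immunoglobulin subunits in plasma cells, stood at 272 ± 338 against 0.174 ± 0.0822 (7.07 ± 0.76 log2 units, adjusted p = 9.9e-06), with the tumor libraries at 63.2, 91.4 and 662. Slfn4 rose by 2.77 ± 0.59.

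Mast cell and basophil genes had 0 members that rose, 6 that fell and 2 that did not pass (camera adjusted p = 8.0e-11), and this call held with an estimated correlation (adjusted p = 0.011). Cpa3 fell by 3.06 ± 0.34, Mcpt8 by 2.35 ± 0.26 and Gata2 by 2.08 ± 0.22 log2 units. Embryonic globins and fetal genes had 0 members that rose, 5 that fell and 1 that did not pass, a call that also held with an estimated correlation (adjusted p = 7.6e-09 preset and 0.0058 estimated), with Mest, an imprinted gene of fetal growth, at -1.56 ± 0.17 and Hmga2 at -1.14 ± 0.21. Megakaryocyte and platelet genes had 0 members that rose, 6 that fell and 7 that did not pass (camera adjusted p = 1.4e-05, 0.20 with an estimated correlation). Thbs1 changed by -3.70 ± 0.42 and Pf4 by -3.68 ± 0.69. Monocyte and macrophage genes had 0 members that rose, 6 that fell and 16 that did not pass (camera adjusted p = 1.9e-05, 0.35 with an estimated correlation). Siglec1 changed by -2.99 ± 0.49, Adgre1 by -3.18 ± 0.61 and C1qc by -2.99 ± 0.60. Interferon genes had 0 members that rose, 3 that fell and 20 that did not pass (camera adjusted p = 7.4e-05, 0.41 with an estimated correlation), with Irf7 at -2.14 ± 0.54, and inflammatory genes had 0 that rose, 2 that fell and 15 that did not pass (camera adjusted p = 0.0016, 0.43 with an estimated correlation). Il1a changed by -2.94 ± 0.57. Neutrophil granule genes had 2 members that rose, 0 that fell and 19 that did not pass (camera adjusted p = 1.2e-04, 0.43 with an estimated correlation). Retnlg rose by 1.86 ± 0.42. None of the 34 cell cycle, 4 globin or 8 NADPH oxidase genes passed. Immunosuppressive mediators had 1 member that rose, 3 that fell and 19 that did not pass (camera adjusted p = 0.25), with Lgals1 at -1.78 ± 0.30 and Il4ra at 1.04 ± 0.25.

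T and NK cell genes had 5 members that rose, 1 that fell and 20 that did not pass (camera adjusted p = 1.1e-04, 0.53 with an estimated correlation), B cell genes had 2 that rose, 1 that fell and 14 that did not pass (camera adjusted p = 0.010, 0.62 with an estimated correlation) and MHC class II genes had 1 that rose, 0 that fell and 7 that did not pass (camera adjusted p = 0.0011, 0.43 with an estimated correlation). Ciita rose by 1.91 ± 0.36. These calls were lost without tumor CD45+ replicate 3 (adjusted p = 0.17, 0.90 and 0.20), and that of B cells without neonatal CD45+ replicate 2 (0.066). Red cell membrane and erythroid transcription genes passed camera as lists (camera adjusted p = 0.017, 0.67 with an estimated correlation for the former and 0.025 and 0.62 for the latter) with 0 and 1 members risen. They did not pass without tumor CD45+ replicate 2 (0.38 and 0.28) or neonatal CD45+ replicate 3 (0.45 and 0.28). Dendritic cell genes (0 rose, 2 fell and 11 did not pass, camera adjusted p = 0.010, 0.52 with an estimated correlation) did not pass without tumor CD45+ replicate 1 (0.20) or neonatal CD45+ replicate 3 (0.10). Glycolysis and hypoxia genes (1 rose, 0 fell and 20 did not pass, camera adjusted p = 0.016, 0.49 with an estimated correlation) did not pass without tumor CD45+ replicate 1 (0.098) or 2 (0.14) or neonatal CD45+ replicate 3 (0.076). With fry 10 of the 14 lists that passed camera here did not pass. In all, 740 of 11195 genes passed at an adjusted p below 0.05, 246 higher and 494 lower in tumor CD45+ cells, and 191 and 391 of these differed at least 2-fold. The count was 429 without tumor CD45+ replicate 2, 1136 without replicate 3, 435 and 431 without neonatal CD45+ replicates 1 and 2, and 2022 with replicates 1 and 2 alone.

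Tumor CD45+ cells were next compared with the MDSC of tumor-bearing mice, the known suppressive myeloid population. They held more erythroid transcripts and far more B cell, T cell and MHC class II transcripts than MDSC, and less of several neutrophil genes. Hbb-bs stood at 4065 ± 461 in tumor CD45+ cells and 137 ± 114 in MDSC (SD, n = 3), a rise of 5.33 ± 0.63 log2 units (SE, adjusted p = 0.0016). Alas2, the erythroid enzyme that starts haem synthesis, stood at 247 ± 52.3 against 8.27 ± 7.22. Cd79a stood at 83.1 ± 77.3 against 1.82 ± 0.504 (4.53 ± 0.49, adjusted p = 0.0011). Alox5ap, needed for leukotriene synthesis, fell by 1.97 ± 0.50 (adjusted p = 0.043), Myadm by 2.19 ± 0.54 and Dach1 by 2.02 ± 0.44 log2 units.

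All 4 globin genes rose (camera adjusted p = 3.3e-05, 0.30 with an estimated correlation). Red cell membrane genes had 15 members that rose, 0 that fell and 4 that did not pass (camera adjusted p = 4.8e-15, 0.29 with an estimated correlation). Slc4a1, the band 3 anion exchanger, rose by 4.74 ± 0.71. Haem synthesis genes had 9 members that rose, 0 that fell and 9 that did not pass (camera adjusted p = 7.6e-06, 0.31 with an estimated correlation). Fech rose by 2.62 ± 0.33. Erythroid transcription and maturation genes had 12 members that rose, 0 that fell and 9 that did not pass (camera adjusted p = 2.4e-09, 0.29 with an estimated correlation). Bpgm rose by 3.91 ± 0.33 and Klf1 by 2.35 ± 0.32. B cell genes had 15 members that rose, 0 that fell and 2 that did not pass (camera adjusted p = 1.6e-14, 0.30 with an estimated correlation), and T and NK cell genes had 17 that rose, 0 that fell and 3 that did not pass (camera adjusted p = 3.7e-13, 0.31 with an estimated correlation). Lck rose by 2.83 ± 0.47. All 8 MHC class II genes rose (camera adjusted p = 2.5e-09, 0.29 with an estimated correlation). Cd74 rose by 4.65 ± 0.53. In the other direction, neutrophil granule genes had 0 members that rose, 4 that fell and 17 that did not pass (camera adjusted p = 5.3e-11, 0.29 with an estimated correlation), and 0 rose and 9 fell adjusted over the list alone, with Mmp9 at -1.65 ± 0.32, Itgam at -1.34 ± 0.26 and Ltf at -1.44 ± 0.35. NADPH oxidase genes had 0 members that rose, 3 that fell and 5 that did not pass (camera adjusted p = 7.7e-06, 0.20 with an estimated correlation). Ncf1 changed by -1.62 ± 0.36 and Cybb by -0.93 ± 0.24. Immunosuppressive mediators had 1 member that rose, 2 that fell and 16 that did not pass (camera adjusted p = 6.9e-04, 0.20 with an estimated correlation). Lgals3 changed by -1.16 ± 0.28 and, higher in tumor CD45+ cells, Cd274, the checkpoint ligand PD-L1, by 1.88 ± 0.46 (adjusted p = 0.036). None of the 34 cell cycle genes passed singly; the list's camera call (camera adjusted p = 7.6e-05, 0.57 with an estimated correlation) was lost without tumor CD45+ replicate 3 (adjusted p = 0.53). Ribosomal protein genes had 1 member that rose, 0 that fell and 79 that did not pass (camera adjusted p = 0.0011, 0.70 with an estimated correlation). Rps27 changed by 1.02 ± 0.25. With fry, which tests each list against no change, the neutrophil, cell cycle and ribosomal lists did not pass (adjusted p = 0.068, 0.53 and 0.15).

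In a limma fit of the 9 libraries from tumor-bearing mice, 658 of 10255 genes passed at an adjusted p below 0.05, 556 higher and 102 lower in tumor CD45+ cells, and 523 and 85 of these differed at least 2-fold. The split was 406 higher and 209 lower under median-ratio scaling, 674 and 77 with haemoglobin genes left out, and 248 and 144 under quantile normalization, with the median of all genes at 0.16, 0.01, 0.23 and -0.04 unscaled and in these 3 settings. Each library of the pair weighed on the count, which was 416, 359 and 303 without tumor CD45+ replicates 1, 2 and 3, 370, 279 and 246 without MDSC replicates 1, 2 and 3, and 258 with replicates 1 and 2 alone.

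How near each Ter119+CD71+ population lay to MDSC was measured as the Spearman correlation across 11294 genes of each library with the mean of the 3 MDSC libraries. It was 0.893 ± 0.0645 in tumor CD45+, 0.833 ± 0.0105 in neonatal CD45+, 0.745 ± 0.0259 in anemia CD45+, 0.598 ± 0.00818 in tumor CD45-, 0.584 ± 0.0149 in anemia CD45- and 0.601 ± 0.0268 in neonatal CD45- libraries (SD, n = 3). The 3 tumor CD45+ libraries stood at 0.936, 0.924 and 0.819 and the anemia CD45+ libraries at 0.731, 0.728 and 0.775. Exact two-sided permutation tests, 3 in the family, gave p = 0.10 for tumor CD45+ against anemia CD45+ and against tumor CD45- libraries (adjusted p = 0.15 for both) and p = 0.40 against neonatal CD45+ libraries (adjusted p = 0.40). With 3 libraries against 3 such a test cannot go under 0.1.

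Whether the CD45 contrast itself differed between states was tested as an interaction. Against anemia, camera placed the neutrophil granule list higher and the T and NK cell and B cell lists lower than other genes, but none of the 3 held with an estimated correlation (adjusted p = 0.20, 0.29 and 0.37), B cells did not pass with fry (0.12), and few lymphocyte genes passed singly. Ltf rose by 2.73 ± 0.46 log2 units more in the tumor state (SE, adjusted p = 0.0049) and Lgals3 by 3.01 ± 0.58 more (adjusted p = 0.012). Tnfrsf13c, the B cell survival receptor BAFF-R, had an interaction of -3.90 ± 0.65 (adjusted p = 0.0049), and Rph3al one of -2.35 ± 0.50.

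Of 21 neutrophil granule genes 10 had a positive and 0 a negative interaction and 11 did not pass (camera adjusted p = 9.9e-15, 0.20 with an estimated correlation), and 14 were positive and 0 negative adjusted over the list alone. T and NK cell genes had 0 positive and 3 negative interactions that passed and 23 that did not (camera adjusted p = 9.0e-16, 0.29 with an estimated correlation), and 0 were positive and 17 negative adjusted over the list alone. Glycolysis and hypoxia genes had 3 positive and 0 negative interactions that passed and 18 that did not (camera adjusted p = 1.6e-04, 0.32 with an estimated correlation). Tpi1 had an interaction of 2.92 ± 0.71. Cell cycle (camera adjusted p = 1.9e-05, 0.49 with an estimated correlation), B cell (camera adjusted p = 1.3e-06, 0.37 with an estimated correlation) and dendritic cell (camera adjusted p = 4.3e-04, 0.39 with an estimated correlation) lists passed with no member past the threshold over all genes. So did the MHC class II list (camera adjusted p = 0.0032, 0.47 with an estimated correlation) and the class I list (camera adjusted p = 0.0069, 0.47 with an estimated correlation), both lost without anemia CD45- replicate 3 (adjusted p = 0.13 and 0.079). The sort antigen list (camera adjusted p = 0.030, 0.25 with an estimated correlation) was lost without tumor CD45+ replicate 2 (0.056) or 3 (0.092), tumor CD45- replicate 3 (0.062) or anemia CD45- replicate 1 (0.072) or 2 (0.056). The mast cell list (camera adjusted p = 0.017, 0.29 with an estimated correlation) was lost under quantile normalization (0.19) and without tumor CD45+ replicate 3 (0.085), tumor CD45- replicate 3 (0.099), anemia CD45+ replicate 2 (0.055) or anemia CD45- replicate 1 (0.063). The NADPH oxidase list (camera adjusted p = 0.031, 0.42 with an estimated correlation) was lost with the replicate block (0.051), under median-ratio scaling (0.058) and without tumor CD45+ replicate 2 (0.054), tumor CD45- replicate 3 (0.092), anemia CD45+ replicate 1 (0.077) or 2 (0.063) or anemia CD45- replicate 1 (0.069) or 2 (0.076).

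With fry 6 of these 11 lists did not pass. In all, 246 of 11195 interactions passed, 202 positive and 44 negative, 166 and 70 under quantile normalization. The count was 99, 89 and 1184 without tumor CD45+ replicates 1, 2 and 3, 143 and 120 without tumor CD45- replicates 1 and 2, 97, 84 and 432 without anemia CD45+ replicates 1, 2 and 3, 111 without anemia CD45- replicate 2, and 1822 with replicates 1 and 2 alone. The positive majority was nearly gone without tumor CD45+ replicate 3 (599 and 585) and smaller with replicates 1 and 2 alone (1020 and 802).

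Against neonates, the CD45 contrast of tumor-bearing mice differed most in mast cell and basophil genes. Cpa3 had an interaction of -2.83 ± 0.49 log2 units (SE, adjusted p = 0.0059) and Gata2 one of -2.07 ± 0.31 (adjusted p = 0.0021), and of the members of that list 0 had a positive and 5 a negative interaction and 3 did not pass (camera adjusted p = 2.3e-13, adjusted p = 0.0058 with an estimated correlation). Mcpt4, which encodes a mast cell chymase, was 10.8, 10.8 and 89.9 in the neonatal CD45+ libraries and 0.00981, 0 and 0 in the tumor CD45+ libraries. In the other direction Slc2a1, the GLUT1 glucose transporter, rose by 4.21 ± 0.51 more in the tumor state (adjusted p = 2.3e-04) and Chd7, a chromatin remodeler, by 3.10 ± 0.34 more. Megakaryocyte genes had 0 positive and 1 negative interactions that passed and 12 that did not (camera adjusted p = 2.9e-05, 0.23 with an estimated correlation). Thbs1 did not pass, at -2.52 ± 0.60 (limma adjusted p = 0.0504). Glycolysis genes had 1 positive and 0 negative interactions that passed and 20 that did not (camera adjusted p = 3.6e-05, 0.30 with an estimated correlation). The NADPH oxidase (camera adjusted p = 0.0073, 0.33 with an estimated correlation) and inflammatory (camera adjusted p = 0.0056, 0.49 with an estimated correlation) lists passed with no member past the threshold.

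The neutrophil granule list (camera adjusted p = 5.9e-04, 0.47 with an estimated correlation) was lost without tumor CD45- replicate 3 (adjusted p = 0.35). The B cell (camera adjusted p = 0.0051, 0.59 with an estimated correlation), T and NK cell (camera adjusted p = 8.7e-04, 0.59 with an estimated correlation) and MHC class II (camera adjusted p = 6.5e-04, 0.41 with an estimated correlation) lists were lost without tumor CD45+ replicate 3 (adjusted p = 0.62, 0.30 and 0.082). The ribosomal protein list (camera adjusted p = 0.030, 0.83 with an estimated correlation) was lost without tumor CD45+ replicate 1 (0.16) or 2 (0.092), tumor CD45- replicate 1 (0.13), neonatal CD45+ replicate 1 (0.11) or 3 (0.091) or neonatal CD45- replicate 1 (0.10) or 2 (0.15). With fry 8 of the 10 lists that passed camera did not pass. In all, 121 of 11195 interactions passed, 57 positive and 64 negative, 110 and 68 with haemoglobin genes left out. The count was 69 and 395 without tumor CD45+ replicates 2 and 3, 77, 65 and 78 without tumor CD45- replicates 1, 2 and 3, 43 and 43 without neonatal CD45+ replicates 1 and 2, 76 without neonatal CD45- replicate 1, and 730 with replicates 1 and 2 alone.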

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

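The tests of a mixture of only CD45- and MDSC RNA, of the liver genes and of the blank values were chosen only after the results were seen. The results below were picked out because the CD45 contrast, CD45+ minus CD45-, differed between states by an interaction test in limma.

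Between tumor-bearing mice and mice with anemia the contrast differed for 246 genes. The contrast was larger in tumor-bearing mice by 5.43 log2 units for BC100530, 4.71 for Ms4a3, 4.38 for Ctsg, 4.38 for Olfm4 and 3.98 for Elane. Ctsg was listed at 0 in all 3 anemia CD45- libraries, so its value depends on the pseudocount. The contrast was smaller for Tnfrsf13c (-3.90), Gzma (-3.51), Rph3al (-2.355), Chd3 (-2.25) and Ifngr2 (-2.23). The 11 lists that differed by camera, none with an estimated correlation and 6 not with fry, had median differences of 2.25 for neutrophil granule and MDSC genes, 1.15 for glycolysis and hypoxia, 1.09 for NADPH oxidase, 1.09 for sort antigens, 0.79 for cell cycle and 0.63 for mast cells and basophils. On the lower side were T and NK cells (-1.51), B cells (-1.29), dendritic cells (-1.03), MHC class II (-0.93) and MHC class I (-0.51). Over 100 splits of status within CD45+ and within CD45- libraries, 7 gave at least 246 genes, the real split included. The highest of the others was 722, from exchanging tumor and anemia in CD45- libraries alone. All 6 other such splits keep the CD45+ libraries as labelled, and CD45+ libraries differ between states whatever the CD45- labels are. Such splits still hold that real difference, so they cannot decide about chance, which was not excluded.

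Between tumor-bearing mice and neonates the contrast differed for 121 genes. The tumor contrast was larger for Jchain (5.09), Lipg (4.23), Slc2a1 (4.21), Tmem40 (3.13) and Chd7 (3.10), and smaller for Mcpt4 (-4.10), Cma1 (-3.93), Clec4f (-3.87), Epx (-3.79) and Tpsb2 (-3.76). Clec4f was listed at 0 in all 3 tumor CD45+ libraries, Lipg in all 3 neonatal CD45- libraries, Cma1 in all 3 tumor CD45- libraries and Tpsb2 in both tumor groups, so these fitted values depend on the pseudocount. Of the 10 lists that differed by camera, only mast cells and basophils passed with an estimated correlation and 8 did not pass with fry. Their medians were 1.14 for MHC class II, 1.08 for neutrophil granule and MDSC genes, 1.01 for NADPH oxidase, 0.83 for T and NK cells, 0.71 for glycolysis and hypoxia, 0.61 for B cells and 0.26 for ribosomal proteins, and -2.21 for mast cells and basophils, -1.14 for megakaryocytes and platelets and -0.27 for inflammatory genes. Over 100 splits 5 gave at least 121 genes, the real split included, with 860 the highest of the others from the exchange in CD45- libraries alone. Chance was not excluded, and all 4 other such splits keep the CD45+ libraries as labelled.

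Leukocyte transcripts were high and erythroid ones low in tumor CD45+ cells. Over 44 erythroid genes that MDSC nearly lack they held a median of 10.2% of the CD45- level. Log2 ratios ran from -3.97 to -1.58, so no single ratio describes all. Their robust SD was 0.398, under the 0.526 between CD45- groups, so dilution by RNA of other cells may contribute. The SD was 0.345 in anemia and, above that limit, 0.601 in neonates. Over 20 neutrophil genes the median level was 41.1% of that in MDSC, with a robust SD of 0.460. The 0.689 limit is between single MDSC libraries and not means, so it cannot show whether MDSC-like cells passed the CD45+ gate. Log2 ratios ran from -2.10 to 0.13. The primary granule genes Ctsg (0.13), Mpo (0.05), Elane (-0.01) and Prtn3 (-0.17) lay near MDSC, so no single ratio describes all 20. The most abundant, S100a9 and S100a8, stood at 9753 ± 4333 and 7599.5 ± 3645 in tumor CD45+ cells and 23714 ± 6867 and 18530 ± 4118 in MDSC (SD, n = 3). RNA from CD45- erythroid cells and MDSC alone is excluded, since 40 of 45 genes of the B cell, T and NK cell and MHC class II lists (88.9%) stood above both populations, against 336 of 10182 of all genes (3.30%), with Cd74 at 505 ± 417 against 6.48 ± 4.52 and 15.5 ± 2.82. The Ter119 and CD71 gates should remove leukocytes, the purity of the sort is not given, and bulk RNA cannot show whether erythroid and myeloid genes share a cell, so erythroid-like cells that themselves express leukocyte genes stay open.

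Liver genes marked the neonatal libraries. Of 24 hepatocyte genes, 22 (91.7%) were higher in all 6 neonatal than in all 12 tumor and anemia Ter119+CD71+ libraries, where chance gives 1.19% for a gene if the CD45+ and CD45- libraries of a number and status count as 1 unit, so hepatocyte RNA may be present there, and the most abundant of the 22 was Alb, at 65.8 ± 59.2 in neonatal CD45+ and 156 ± 162 in CD45- cells (SD, n = 3), with none of those 12 libraries above 0.730. Median log2 CD45+ to CD45- ratios of hepatocyte and Kupffer cell genes were -0.92 and 3.72, a difference of 4.63. This argues against free liver RNA as the sole but not as a partial source. Age differs between these groups by design, the labels name spleen as the tissue, a Kupffer cell would pass a CD45 gate though the Ter119 and CD71 gates should remove both liver cell types, and no gene of these lists is in another list. In those 12 libraries 2 of the hepatocyte and 4 of the Kupffer cell genes reached 1, so liver cells in the sort and a neonatal spleen that expresses these genes both stay open.

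Blank values in abundant genes fell on single-exon genes. Of 53 genes with a blank beside a value of at least 20 in another library of the same group, 52 could be matched to a gene model and 51 of these (98.1%) had a single-exon coding transcript, against 41 of 4820 other genes reaching 20 (0.851%, two-sided Fisher's exact test p = 2.1e-94). The authors' quantification may therefore lose single-exon genes in some libraries. The 28 histone genes among them are not read as falls. No biological explanation was tested.

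For the single comparisons 10 splits of 6 libraries cannot give a share under 0.05, and 1 split, the real one, reached its count in each. The real count and the highest other were 6839 and 1 for tumor, 6577 and 1 for anemia and 6710 and 39 for neonatal CD45+ against CD45- cells. They were 1201 and 167 for tumor against anemia CD45+ cells, 740 and 179 for tumor against neonatal CD45+ cells and 658 and 7 for tumor CD45+ cells against MDSC.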

How the results depend on the processing

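The fits of replicates 1 and 2 alone, the fits without genes with blanks beside high values and the list tests without each library were chosen only after the data were seen. In the alternatives run the direction in which camera placed a passing list and the sign of the similarity differences stayed. List medians changed sign for 3 of 108 passing lists. They were, in the tumor CD45 contrast, EPO-STAT5 targets (0.40, to -0.61 under quantile normalization and -0.06 without tumor CD45- replicate 1) and antioxidant genes (0.01, to -0.43 under median-ratio scaling, -0.65 under quantile normalization, -0.03 and -0.15 without tumor CD45+ replicates 1 and 2 and -0.08 and -0.08 without tumor CD45- replicates 1 and 2), and against MDSC the cell cycle list (-0.37, to 0.11 without tumor CD45+ replicate 3). The balance of higher and lower genes turned under quantile normalization in all 3 contrasts of CD45+ with CD45- cells (2617 and 3060, 2647 and 2990 and 2663 and 2808). It turned for tumor against anemia CD45+ cells without tumor CD45+ replicate 3 (1024 and 1203) and with replicates 1 and 2 alone (1663 and 1845), and in 7 of 24 alternatives for the interaction with neonates, among them 198 and 197 without tumor CD45+ replicate 3 and 84 and 42 without neonatal CD45+ replicate 3. For the genes named in the report and here, 3225 of 3507 results kept direction and side of the threshold, 266 no longer passed, 12 passed only under the alternative and 4 reversed. These 4 were all Tfrc in tumor against anemia CD45+ cells, which had not passed and lay at -0.03 log2 units, at 0.22 and 0.05 without tumor CD45+ replicates 1 and 3 and 0.05 and 0.24 without anemia CD45+ replicates 1 and 2. Over all alternatives it ran from -0.39 to 0.24. The counts for CD45+ against CD45- cells stayed within 1.5 times, at 5196 to 7566 genes in tumor-bearing mice, 5079 to 7504 in anemia and 5130 to 7567 in neonates. Over all 8 comparisons 102 of 156 gene counts stayed within that bound, 41 were lower and 13 higher. The cause was not tested, except that a stricter filter leaves fewer genes to test by construction. Fewer libraries could raise a count, as without tumor CD45+ replicate 3 (1201 to 2227 for tumor against anemia CD45+ cells).

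Tumor against anemia CD45+ cells gave 1201 genes, 723 with a pseudocount of 0.1, 744 with the strict filter, 75 with only the compared groups and 3508 with replicates 1 and 2 alone. Leaving out 1 library gave 546 to 2227. Tumor against neonatal CD45+ cells gave 740 genes, 1238 without a filter, 370 with the strict filter, 140 with only the compared groups and 2022 with replicates 1 and 2 alone. Leaving out 1 library gave 429 to 1136. Tumor CD45+ cells against MDSC gave 658 genes, 392 under quantile normalization, 401 with the strict filter, 238 with only the compared groups, 1109 with all 21 libraries and 258 with replicates 1 and 2 alone. Leaving out 1 library gave 246 to 416.

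The interaction with anemia gave 246 genes, 61 with a pseudocount of 0.1, 162 with the strict filter, 114 with only the compared groups, 384 with all 21 libraries and 1822 with replicates 1 and 2 alone. Leaving out 1 library gave 84 to 1184. The interaction with neonates gave 121 genes, 233 without a filter, 68 with the strict filter, 70 with only the compared groups and 730 with replicates 1 and 2 alone. Leaving out 1 library gave 43 to 395. The report names each library whose absence moved these 5 counts by over 1.5 times, with the count without it.

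Of 207 list tests 108 passed with camera, 4 with an estimated correlation, 115 under median-ratio scaling, 122 under quantile normalization, 102 with fry and 104 to 119 without a library. Over single lists 2608 of 2808 results kept camera's direction and side of the threshold and 200 no longer passed. Fry ended red cell membrane (0.52), erythroid (0.45), neutrophil (0.13), B cell (0.38), T and NK (0.29), dendritic cell (0.11), interferon (0.068), MHC II (0.12), glycolysis (0.30) and inflammatory (0.092) against neonatal CD45+ cells, cell cycle (0.17), NADPH oxidase (0.075), B cell (0.12), dendritic cell (0.12), MHC I (0.20) and MHC II (0.24) for the interaction with anemia and NADPH oxidase (0.061), neutrophil (0.22), B cell (0.39), T and NK (0.38), MHC II (0.17), glycolysis (0.068), inflammatory (0.40) and ribosomal (0.67) for that with neonates, besides EPO-STAT5 in the tumor CD45 contrast (0.89), cell cycle against anemia (0.11) and cell cycle (0.53), neutrophil (0.068) and ribosomal (0.15) against MDSC. The similarity difference of 0.148 between tumor and anemia CD45+ libraries moved to 0.0876 without a filter and 0.228 with the strict filter. The other 26 of 28 such values stayed within 1 SD between libraries, though the difference of 0.0602 between tumor and neonatal CD45+ libraries was 0.0386 and 0.0973 without tumor CD45+ replicates 1 and 3.

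With the replicate block, which pairs libraries of the same number, the counts were 7199, 6935 and 7113 for CD45+ against CD45- cells in tumor, anemia and neonates, 1469 and 868 for tumor against anemia and neonatal CD45+ cells, 744 for MDSC, and 287 and 141 for the interactions, and 110 lists passed. The block ended the glycolysis call in anemia (adjusted p = 0.056, 3.0e-05 to 0.57 over all alternatives) and the NADPH oxidase call of the interaction with anemia (0.051, 0.0027 to 0.42), and no other list call that had passed. It also covered tumor and anemia CD45+ libraries, taken as unpaired. Depth is unknown, so what it limits cannot be stated.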

Other observations

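No test in this part was chosen after its result was seen except the liver gene lists. The CD45 contrast was largely shared by the 3 states. Of 11195 genes 4059 were higher in CD45+ cells in all 3, against 1323 by chance if calls were independent, and 772 lower, against 14.2. Quantile normalization left 2617 to 2663 higher calls per state, so the 4059 depends on scaling. Genes passing in opposite directions numbered 8 between tumor and anemia, 4 between tumor and neonates and 18 between anemia and neonates. Pearson coefficients of log2 fold changes across genes, which are not independent replicates, were 0.867, 0.901 and 0.814 for these pairs.

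Kupffer cell genes, of macrophages resident in the liver, were a further feature of neonatal CD45+ cells. Cd5l, a secreted macrophage protein, stood at 452 ± 110.0 in neonatal CD45+ and 29.2 ± 2.92 in neonatal CD45- cells, Folr2, a folate receptor, at 25.3 ± 9.60 and 2.01 ± 0.877, and Vsig4, a complement receptor, at 66.8 ± 15.0 and 8.05 ± 4.17 (SD, n = 3). Of the 8 Kupffer cell genes, 5 (62.5%) were higher in all 6 neonatal than in all 12 tumor and anemia Ter119+CD71+ libraries. Cd5l reached 55.4 and C6 42.5 among those 12 libraries, so these genes are not absent there. The fetal and hepatic carrier gene Afp stood at 22.7 ± 21.5 in neonatal CD45+ and 38.9 ± 35.8 in CD45- cells (SD, n = 3), with none of those 12 libraries above 0.969.

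The stress and immediate early list passed in none of the 8 comparisons as fitted, but under quantile normalization it was placed higher in all 3 CD45 contrasts (camera adjusted p = 0.012 in tumor, 0.0020 in anemia and 0.0036 in neonates). In it 10 of 17 genes rose and 1 fell in the CD45 contrast of tumor-bearing mice (camera adjusted p = 0.34 as fitted), and in anemia and neonates 11 and 10 rose (camera adjusted p = 0.099 and 0.18 as fitted). Whether the list differed from other genes thus depended on scaling.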
